A study of Homo sapiens with 6 samples.

How the data were processed

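RNA was measured in 6 libraries of HEK293T, a human embryonic kidney line that carries the SV40 large T antigen. The cells had received RfxCas13d, a CRISPR effector that cuts RNA matched by its crRNA. In 3 libraries the crRNA was non-targeting, and in 3 it was directed at mCherry, the mRNA of a red fluorescent protein that the human genome does not encode. Per the labels' protocols, cells were grown at 37 °C in 10% CO2 with 10% serum, and total RNA was extracted with Trizol, DNase-treated and enriched for poly(A) RNA. The libraries were strand-marked with dUTP and primed at random, so that reads cover whole transcripts and their number depends on transcript length and, through PCR, on GC content.

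The authors deposited raw counts per gene, not normalized, in a single table with a column per library. Per the submitters' processing notes, cutadapt 4.4 and STAR 2.7.4a were used with the hg19 (GRCh37) genome. The counting tool and its strand setting are not given in the sources used here, so counts of overlapping and antisense genes, and of genes with near-identical copies, are uncertain. The table holds 57820 versioned Ensembl identifiers, of which 47 are copies from the Y pseudoautosomal region with a summed count of 0. The identifiers were matched without their version to a reference annotation on GRCh38. Of them, 51996 matched and 39538 carried a symbol. Gene names, transcript length, GC content and coordinates come from that annotation, and all coordinates are GRCh38. GC content and length refer to the longest transcript and were known for 96.0% of the genes tested. A row for mCherry or RfxCas13d was not analysed here.

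Counts were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes with low counts were removed by filterByExpr, and 19676 genes were tested. The quasi-likelihood F test with robust dispersion compared the 3 mCherry-targeting with the 3 non-targeting libraries, with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. Values per library are CPM (counts scaled to a common library total) after TMM scaling. Means carry the SD over 3 libraries and log2 fold changes the standard error (SE) of the fit. A share of counts was compared between groups by an exact two-sided permutation test over 20 assignments, whose smallest p for 3 against 3 is 0.1. The 7 such library measures were adjusted together.

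Gene lists were fixed before the data were examined, 24 in number. They cover stress and inflammatory programmes, mitochondrial and ribosomal genes, non-coding RNAs, zinc finger genes, cell cycle, sterol, glycolytic and antioxidant genes, reference genes, and markers of blood, fibroblast and hepatocyte or other epithelial cells. Lists with at least 5 tested members, 22 in all, were tested by camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, and again with the correlation estimated from each list. Members passing were counted over all genes tested and adjusted over the list alone. Medians and means of a list are those of the fitted log2 fold changes.

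Genes were named by a rule also fixed before the data were examined. It took any mCherry or RfxCas13d row, up to 8 called genes in each direction with a mean CPM of at least 5 and no overlap between the groups, the 3 leading called members of up to 6 called lists, and the leading called member of every other list. This rule gave HMOX1 and MAP1A. All other genes named were chosen after their values were seen, as members that passed adjusted over the list alone, as members with the smallest p in a called list, as examples of a list, or, outside the lists, for a large fold change, a known role in redox metabolism or a call with the library set term.

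Alternatives listed before the data were examined were size factors of the DESeq2 type, library sizes alone, upper-quartile factors, no filter, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, a block for the replicate number, leaving out each library in turn, and for the lists an estimated correlation, fry and a rank-based camera. Other denominators and the 50 most abundant genes were tried for the shares of counts. Chosen after seeing the data were a correction for GC content, one for GC content and length, the block with the GC correction, a term separating libraries with a 7SK share above and below 1%, and the same term with the GC correction. The GC correction removed from each library a smoothed (loess, span 0.5) trend on GC content of log2 CPM relative to each gene's mean over the libraries. Leaving out each library for the shares of counts was also added then.

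Total counts per library lay between 21321850 and 25906275, and the common biological coefficient of variation was 0.113. The fit was tested on counts simulated for the mCherry-targeting against non-targeting comparison at the real means and library sizes. Among 19345 simulated genes in the fit, it recovered 70.1% of 67 genes changed 1.5-fold, 98.5% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 16 false calls. The changed genes were drawn only from those with a mean CPM of at least 5, so recovery at lower levels was not measured. The ribosome biogenesis list was shifted as well, and its members are not counted as false calls. Recovery depends on how many genes change, because the Benjamini-Hochberg cutoff is looser when many do. The real data gave 2 calls, so recovery there can be lower. When the GC trend of each library was added to the simulation, the uncorrected fit made 99 false calls and the GC-corrected fit 20. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 9.61 to 41.1, and each was counted as 1 sample. The labels call them biological replicates and do not say whether cultures were separate transfections.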

Results

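Poly(A)-enriched RNA was sequenced from HEK293T cells with RfxCas13d and either a non-targeting crRNA (3 libraries) or a crRNA directed at mCherry (3 libraries). The comparison asks which endogenous transcripts differ when the effector is supplied with a crRNA for an mRNA foreign to the human genome. Whether the cells held an mCherry mRNA is not given in the sources used here. Non-targeting replicates 1 to 3 held 21321850, 25906275 and 24477525 counts, and mCherry-targeting replicates 1 to 3 held 23252447, 24974595 and 24256965. Between 28393 and 29453 genes had at least 1 count in a library. The groups did not differ detectably in total counts (exact permutation test, two-sided p = 0.9; adjusted over 7 library measures, p = 1), and 3 libraries against 3 cannot give a p under 0.1.

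HMOX1, the inducible heme oxygenase that degrades heme and is a target of the antioxidant regulator NRF2, was lower in the mCherry-targeting libraries. Its level was 23.7 ± 2.14 CPM (SD, n = 3) in the non-targeting and 6.05 ± 1.22 CPM (SD, n = 3) in the mCherry-targeting libraries, 3.93-fold lower. MAP1A, which encodes a microtubule-associated protein best known from neurons, was 39.7 ± 6.06 CPM (SD, n = 3) and 20.4 ± 1.06 CPM (SD, n = 3), 1.94-fold lower. The log2 fold change was -1.97 ± 0.15 (SE) for HMOX1 and -0.96 ± 0.12 for MAP1A, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000389 and 0.0319. For both genes all 3 mCherry-targeting libraries lay below all 3 non-targeting ones. HMOX1 (ENSG00000100292.12) lies on chromosome 22, from 35380361 to 35394214 on the plus strand of GRCh38, and MAP1A (ENSG00000166963.8) on chromosome 15, from 43510958 to 43531620 on the plus strand. No other gene of the table that matched the annotation overlaps either of them.

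**Figure D1:**
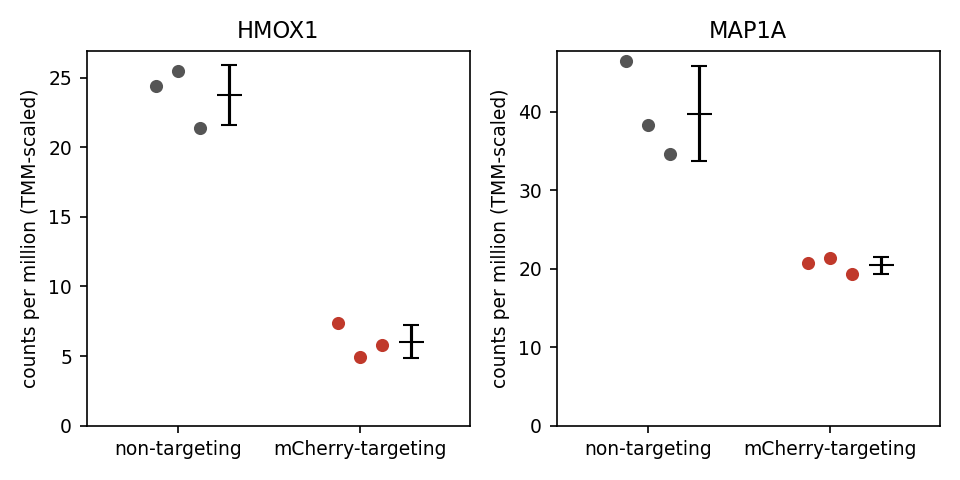
Expression of HMOX1 and MAP1A in TMM-scaled CPM, with a point for each library and a bar for the mean ± SD of 3 libraries. HMOX1 averaged 23.7 CPM in the non-targeting and 6.05 CPM in the mCherry-targeting libraries, and MAP1A 39.7 and 20.4 CPM.

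These were the 2 genes called among 19676, both lower, and HMOX1 alone changed at least 2-fold. The edgeR test called 0 genes higher, while 1969 of the 3167 genes with an unadjusted p under 0.05 were higher. DESeq2 called 173 genes, 138 of them higher, and limma-voom called 1, a lower one. The call for HMOX1 held in each of the 19 alternative fits, and that for MAP1A in 11 of them. MAP1A had log2 fold changes from -1.05 to -0.81 over those fits and an edgeR adjusted p of 0.267 after correction for GC content. Its edgeR adjusted p was 0.383 without non-targeting replicate 2 and 0.26, 0.308 and 0.0943 without mCherry-targeting replicates 1, 2 and 3. Without non-targeting replicate 1, edgeR called 1806 genes, 1141 of them higher, against at most 2 without any other library. It is the only non-targeting library with a 7SK share below 1%, as in mCherry-targeting replicates 1 and 2. Without it, group cannot be told apart from that difference between libraries.

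Fold changes followed the GC content of the transcripts. Among genes with a mean log2 CPM over 1, the 273 with a GC content of up to 35% had a median log2 fold change of 0.30, and the 1483 between 60% and 65% had one of -0.17. Spearman's correlation of fold change with GC content was -0.57 across 18893 genes and -0.74 across the 12073 protein-coding genes with a mean log2 CPM over 1. Genes are not independent replicates, and these correlations carry no p-value. Slopes on GC content were taken for log2 CPM relative to each gene's mean over the 6 libraries, so they measure only differences between libraries. Per 10 percentage points the slope was -0.0065, 0.066 and 0.18 in non-targeting replicates 1 to 3 and -0.10, -0.092 and -0.043 in mCherry-targeting replicates 1 to 3. The group means differed by -0.16 (exact permutation test, two-sided p = 0.1, the smallest possible; adjusted over 7 library measures, p = 0.7). The median GC content was 48.1% over all tested genes. It was 52.5% in the integrated stress response list, 52.6% in the NF-kB list and 43.2% in the G2/M list, and other list medians are given with some of the lists.

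**Figure D2:**
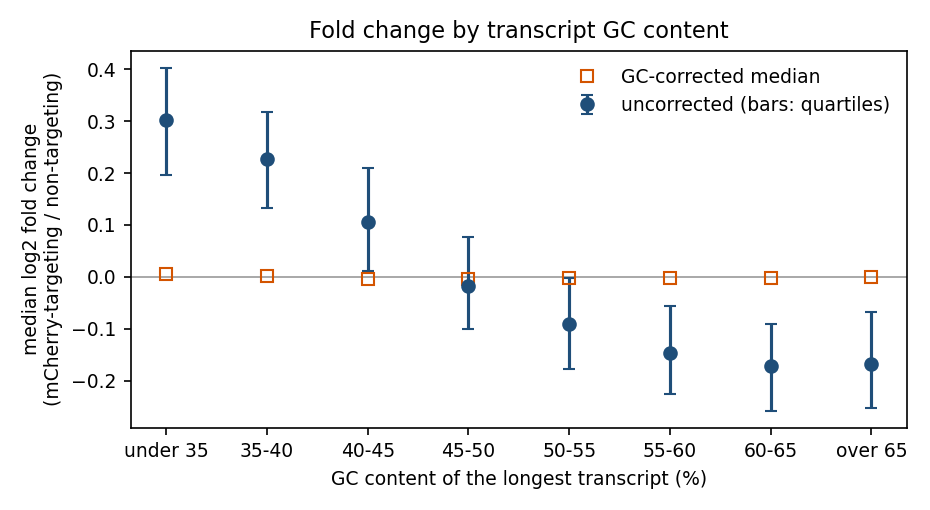
Median log2 fold change (mCherry-targeting against non-targeting) of the 14095 tested genes with a mean log2 CPM over 1, by GC content of the longest transcript, in percent. Filled points and bars are medians and quartiles without correction, open squares the medians after GC correction; the uncorrected medians run from 0.30 at the lowest GC content to -0.17 between 60% and 65%.

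Genes of the NRF2 oxidative stress response, the list that holds HMOX1, were mostly below 0, without a call for the list before GC correction. Of 19 tested members 14 had a log2 fold change below 0, the median was -0.085 and the camera adjusted p was 0.0728 (adjusted p = 0.947 with an estimated correlation). HMOX1 was the 1 member passing over all genes tested, and 2 passed adjusted over the list alone, HMOX1 and MAFG, a small MAF partner of NRF2. The log2 fold change of MAFG was -0.40 ± 0.09, and -0.25 ± 0.07 after GC correction. After GC correction the list was called lower, with a median of -0.098 and a camera adjusted p of 0.0138 (adjusted p = 0.959 with an estimated correlation). With a term for the library set (7SK share above or below 1%) added to the GC correction, the median was -0.0042 and the call ended (camera adjusted p = 0.297). GCLM, a subunit of the enzyme that starts glutathione synthesis, was 31.2 ± 3.27 and 31.4 ± 0.567 CPM (SD, n = 3 each). At its GC content of 37.3%, its log2 fold change was -0.24 ± 0.09 after GC correction. The thioredoxin reductase gene TXNRD1 had a log2 fold change of 0.0089 ± 0.086, and the ferritin light chain gene FTL one of -0.41 ± 0.20. After GC correction these were -0.032 ± 0.081 and -0.27 ± 0.17.

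Other stress programmes were not called. The integrated stress response list (ATF4 targets) had a median log2 fold change of -0.095 over 38 genes (camera adjusted p = 0.0899). Within it, the asparagine synthetase gene ASNS was 734.4 ± 85.3 CPM and 672.0 ± 34.1 CPM (SD, n = 3 each), and the log2 fold change of DDIT3, which encodes the transcription factor CHOP, was -0.0066 ± 0.28. The 20 genes of the endoplasmic reticulum unfolded protein response had a median of -0.0047 (camera adjusted p = 0.908), with the chaperone gene HSPA5 at -0.092 ± 0.10. The 25 p53 targets had a median of 0.17, with 19 above 0 (camera adjusted p = 0.267), and CDKN1A and MDM2 within the list were -0.36 ± 0.19 and 0.21 ± 0.18. Immediate early genes had a median of -0.063 over 39 genes at a median GC content of 55.1% (camera adjusted p = 0.267), and of 0.023 after GC correction (camera adjusted p = 0.718). FOS, JUN and EGR1 had log2 fold changes of -0.16 ± 0.23, 0.13 ± 0.12 and 0.45 ± 0.22.

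The interferon list had a median log2 fold change of -0.085 over 25 tested genes (camera adjusted p = 0.836). IFIT1 and ISG15, both induced by interferon, were at 2.36 ± 0.269 and 3.75 ± 0.346 CPM in the non-targeting libraries, and at 2.19 ± 0.615 and 3.18 ± 0.480 CPM in the mCherry-targeting ones (SD, n = 3). NF-kB and inflammatory genes had a median of -0.017 over 17 genes (camera adjusted p = 0.651). The NF-kB subunit gene RELB passed adjusted over the list alone, the 1 member to do so, with a log2 fold change of -0.90 ± 0.20 and an edgeR adjusted p of 0.193 over all genes. After GC correction RELB was at -0.72 ± 0.19. The heat shock list had a median of -0.020 over 18 genes (camera adjusted p = 0.821). Adjusted over the list alone, 3 of its members passed, HSP90AA1 (0.28 ± 0.09), HSPA4L (0.44 ± 0.11) and CHORDC1 (0.40 ± 0.11). HSPA4L and CHORDC1, both of low GC content (38.1% in HSPA4L), had log2 fold changes of 0.22 ± 0.08 and 0.12 ± 0.07 after GC correction.

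Mitochondrially encoded mRNAs had a median log2 fold change of 0.0073 over 13 genes, 7 of them above 0 (camera adjusted p = 0.876). Their share of all counts was 0.867% ± 0.0825 and 0.836% ± 0.0780 (SD, n = 3 each; exact permutation test, two-sided p = 1; adjusted p = 1). Nuclear-encoded oxidative phosphorylation genes had a median of -0.049 over 48 genes (camera adjusted p = 0.836). With the library set term and GC correction they were called as higher at 0.037 (camera adjusted p = 0.0211; adjusted p = 0.939 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.12, with 60 of 78 below 0 (camera adjusted p = 0.0735), and after GC correction were called lower at -0.078 (camera adjusted p = 0.0461; adjusted p = 0.959 with an estimated correlation). The direction turned with the library set term added, to a call as higher at 0.072 (camera adjusted p = 0.00182; adjusted p = 0.939 with an estimated correlation). Their share of counts was 4.29% ± 0.883 and 3.86% ± 0.601 (SD, n = 3 each; exact permutation test, two-sided p = 0.7; adjusted p = 0.98). This share varied within groups, with 3.31%, 4.52% and 5.03% in non-targeting replicates 1 to 3 and 3.43%, 3.61% and 4.54% in mCherry-targeting replicates 1 to 3. The non-coding RNA 7SK, which is not polyadenylated, varied alongside, with 0.516%, 1.15% and 1.37% of counts and 0.716%, 0.439% and 1.15%. The library set term, cut at a 7SK share of 1%, therefore also separates the libraries by their ribosomal protein share. The direction of the ribosomal protein list with that term is not an independent result. The 10 most abundant genes of a library took 6.27% ± 0.636 and 5.89% ± 0.535 of its counts (SD, n = 3 each; exact permutation test, two-sided p = 0.5; adjusted p = 0.875).

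**Figure D3:**
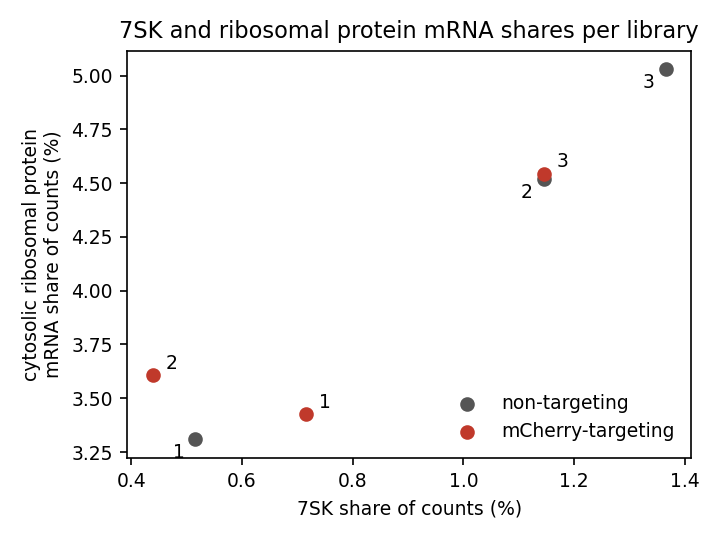
Share of counts in 7SK (horizontal, percent) and in mRNAs of cytosolic ribosomal proteins (vertical, percent), with a point per library numbered by replicate. Non-targeting replicate 1 and mCherry-targeting replicates 1 and 2 have a 7SK share of at most 0.716%, the other libraries of at least 1.15%.

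Ribosome biogenesis genes had a median log2 fold change of 0.038, with 21 of 33 above 0 (camera adjusted p = 0.0899). The nucleolar factor genes DDX21 (0.37 ± 0.08) and WDR43 (0.30 ± 0.08) passed adjusted over the list alone, the 2 members to do so. After GC correction the list median was 0.087, with a camera adjusted p of 0.0073 (adjusted p = 0.959 with an estimated correlation), and DDX21 and WDR43 were at 0.22 ± 0.08 and 0.14 ± 0.07. Replication-dependent histone genes had a median of -0.14 over 13 genes (camera adjusted p = 0.445). Nuclear-retained long non-coding RNAs had a median of 0.12 over 11 genes at a median GC content of 43.1% (camera adjusted p = 0.256), with MALAT1 at 0.21 ± 0.15 and NEAT1 at -0.12 ± 0.13. Host transcripts of snoRNAs had a median of 0.020 over 18 genes (camera adjusted p = 0.839).

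By camera with the preset correlation 2 of the 22 tested lists were called, zinc finger (ZNF) genes as higher and glycolysis and hypoxia genes as lower. The 393 tested ZNF genes had a median log2 fold change of 0.12, with 260 above 0, and the 24 glycolysis and hypoxia genes one of -0.23, with 19 below 0. The camera adjusted p was 0.00347 for each, and adjusted p = 0.947 with an estimated correlation for each. The median GC content was 43.9% in the ZNF list and 52.9% in the glycolysis and hypoxia list, and after GC correction the medians were 0.067 (camera adjusted p = 0.0137) and -0.15 (camera adjusted p = 0.0073), with adjusted p = 0.959 with an estimated correlation for each. With the library set term added neither list was called, with medians of 0.019 and -0.085 (camera adjusted p = 0.403 and 0.105). No member of either list passed, over all genes or adjusted over the list alone. The members with the smallest p were ZNF367 (0.49 ± 0.10), ZNF184 (0.53 ± 0.11) and ZNF268 (0.64 ± 0.14), and the glycolytic regulator and enzyme genes PFKFB4 (-0.49 ± 0.14), ALDOA (-0.44 ± 0.14) and ALDOC (-0.36 ± 0.13). Without non-targeting replicate 3 the ZNF median was 0.062 (camera adjusted p = 0.109) and the glycolysis and hypoxia median -0.13 (0.0625), and without mCherry-targeting replicate 1 they were 0.066 and -0.14 (0.103 for each). Without non-targeting replicate 1 they were 0.18 and -0.32 (camera adjusted p = 8.4e-05 for each). Leaving out that library leaves only non-targeting libraries with a 7SK share above 1%, so those values mix group with library set.

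Cell cycle genes were not called before GC correction. G1/S and DNA replication genes had a median log2 fold change of 0.052 over 24 genes (camera adjusted p = 0.518), and G2/M and mitosis genes one of 0.016 over 27 genes (camera adjusted p = 0.668). The G2/M median hides changes in both directions, with 14 genes above 0 and 13 below. Of the 27, 13 had an edgeR unadjusted p under 0.05, against 3167 of all 19676 tested genes. In the mixed test of fry, which counts changes in either direction, the adjusted p of the G2/M list was 0.191. The mitotic kinase gene PLK1 was at -0.35 ± 0.09, and at -0.20 ± 0.07 after GC correction. After GC correction G1/S genes were called higher (median 0.062, camera adjusted p = 0.0351) and G2/M genes lower, with the median turned to -0.053 (camera adjusted p = 0.0138), each with adjusted p = 0.959 with an estimated correlation. Both calls ended with the library set term added (camera adjusted p = 0.0983 and 0.105). Cholesterol synthesis genes had a median of -0.084 over 22 genes (camera adjusted p = 0.836), and of 0.0091 after GC correction (camera adjusted p = 0.919). The sterol desaturase gene SC5D passed adjusted over the list alone, the 1 member to do so (0.36 ± 0.08, and 0.15 ± 0.08 after GC correction). Reference genes had a median of -0.13, with 21 of 26 below 0 (camera adjusted p = 0.0604), and after GC correction were called lower at -0.092 (camera adjusted p = 0.0073; adjusted p = 0.959 with an estimated correlation). With the library set term added they were at -0.047 and not called (camera adjusted p = 0.297). Among them ACTB, GAPDH and EEF1A1 had log2 fold changes of -0.18 ± 0.12, -0.34 ± 0.17 and -0.38 ± 0.13. After GC correction these were -0.052 ± 0.10, -0.18 ± 0.15 and -0.39 ± 0.13.

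Markers of other cell types were few. Fibroblast markers had a median log2 fold change of -0.19 over 7 tested genes at a median GC content of 53.2% (camera adjusted p = 0.267). After GC correction the median was -0.025 (camera adjusted p = 0.678). TAGLN passed adjusted over the list alone (-0.51 ± 0.15, and -0.37 ± 0.16 after GC correction). Of 15 blood cell markers 3 were tested, with a median of -0.077, and of 13 hepatocyte and epithelial markers 4 were, with a median of 0.011 and KRT8 passing adjusted over the list alone (-0.42 ± 0.14, and -0.28 ± 0.12 after GC correction). These last lists were too short for camera. Adjusted over the list alone, 11 genes passed in the 24 lists, 1 of which, HMOX1, passed over all genes tested. With an estimated correlation the adjusted p was 0.947 for each of the 22 lists. The sign of the camera test differed from that of the median for the mitochondrially encoded, unfolded protein response, heat shock, and G2/M lists, and the mean differed in sign from the median for the NF-kB, heat shock, and G2/M lists.

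**Figure D4:**
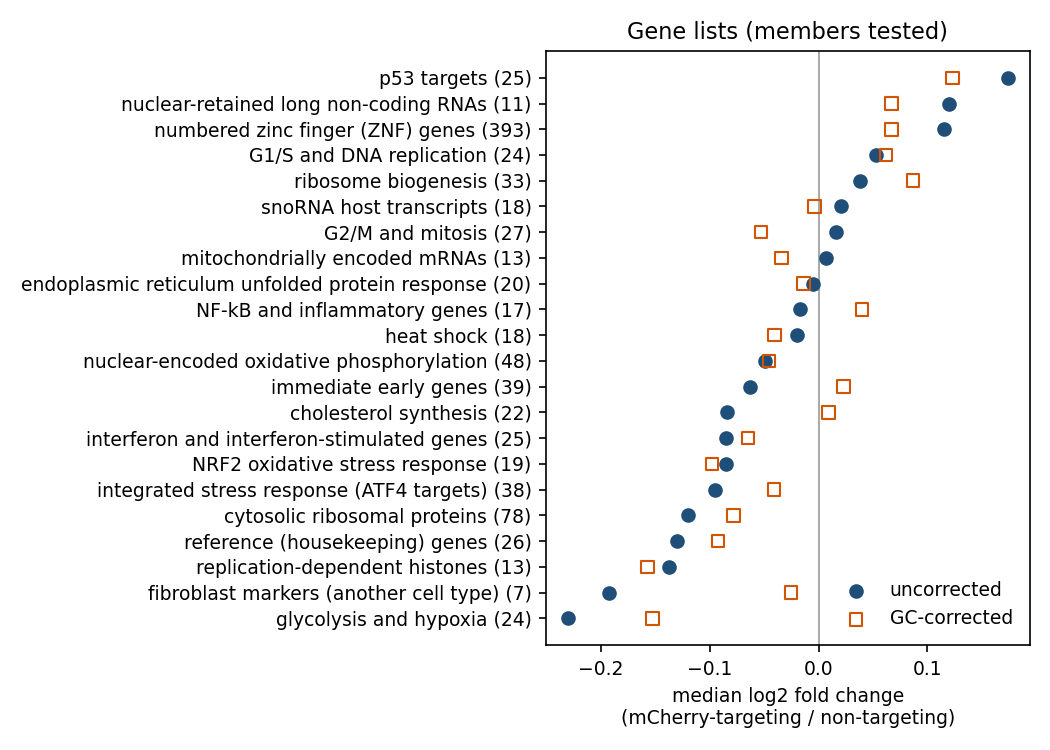
Median log2 fold change (mCherry-targeting against non-targeting) of each gene list tested by camera, with the number of tested members in brackets. Filled points are without and open squares with GC correction; the lowest uncorrected median is -0.23 for glycolysis and hypoxia genes.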

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

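The GC corrections, the library set term (7SK share above or below 1%) and leaving out libraries for the shares of counts were chosen after the data were seen. Against 2 called genes (1 of at least 2-fold), library sizes alone, a mean CPM of at least 5, limma-voom and the GC correction gave 1 each. More were called with no filter (597, of which 26 at least 2-fold), DESeq2 (173), the library set term (712 and 27) and that term with GC correction (40 and 5); the cause was not tested, but the median GC content of calls without GC correction (no filter, DESeq2, library set term, replicate block) was 37.7% to 38.5% for higher and 58.6% to 59.6% for lower genes. Leaving out each library gave 1 to 1806 called genes and 1 to 52 of at least 2-fold, the highest without non-targeting replicate 1. Without that library the non-targeting group holds only libraries with a 7SK share above 1%, so those calls are not separable from the library sets. HMOX1 kept log2 fold changes from -2.14 to -1.83 in 19 alternatives, with adjusted p up to 0.0149; MAP1A (-1.05 to -0.81, adjusted p up to 0.383) was not called with library sizes alone (0.137), a mean CPM of at least 5 (0.18), limma-voom (0.0813) or GC correction (0.267), nor without non-targeting replicate 2 (0.383) or mCherry-targeting replicates 1, 2 or 3 (0.26, 0.308 and 0.0943). Against 2 called lists, library sizes alone gave 6, GC correction 8, GC and length correction 8, the estimated correlation 0 and fry 0 (its mixed test gave 2, NRF2 targets, HMOX1 included, at adjusted p = 0.000485 and ribosome biogenesis at 0.0224), and GC correction with an estimated correlation 0; leaving out each library gave 0 to 8. The ZNF call ended with the library set term (median 0.063, adjusted p = 0.07) and, with GC correction added, at 0.019 (0.403), where the glycolysis and hypoxia call ended too (-0.085, 0.105). The library set term turned nuclear-encoded oxidative phosphorylation genes to a median log2 fold change of 0.067, called as higher, and with GC correction that list (0.037) and cytosolic ribosomal protein genes (0.072) were called as higher (adjusted p = 0.939 with an estimated correlation for each). For ribosomal protein genes the call is not independent of the term, which also separates the libraries by their ribosomal protein share. The replicate numbers share no stated culture or day, and the deviations of same-numbered libraries correlated at 0.230, 0.043 and 0.329. Non-targeting replicates 1 and 3 correlated best with their own numbers. Non-targeting replicate 2 correlated about equally with mCherry-targeting replicates 2 (0.0430) and 3 (0.0448). Libraries numbered 1 share a library set, as do those numbered 3, but those numbered 2 do not, so pairing by number stays open. A replicate block gave 1209 called genes (30 of at least 2-fold) and 5 lists, and with GC correction 6 genes (3 of at least 2-fold) and 7 lists. Differences in the shares of counts stayed within the spread between replicates in the alternatives tried with all libraries. Without non-targeting replicate 1 the 7SK shares no longer overlapped, at 1.1458% or more against at most 1.1454%. Without it the ribosomal protein shares were 4.52% and 5.03% against 3.43%, 3.61% and 4.54%. The simulated recovery of 70.1% for 1.5-fold and 98.5% for 2-fold changes held no GC trend or library sets. It covered only changed genes with a mean CPM of at least 5, depends on the number of genes changed, and is not a bound on what the real libraries can miss.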

Other observations

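The tests of GC content, of splits for the GC-corrected lists, of the library sets, of the NRF2 list without HMOX1 and of the mitochondrial mRNAs, and the genes of the next paragraph, were chosen after the results were seen; the other splits, the neighbouring genes and the non-coding slope were set before their outcome was known.

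Some genes outside the lists had large fold changes without being called. CYP4F3 and CYP4F2, both on chromosome 19 and for fatty acid hydroxylases, had log2 fold changes of 2.96 ± 0.47 and 2.14 ± 0.48, with 0.452 ± 0.0563 and 3.54 ± 2.20 CPM for CYP4F3 and 0.408 ± 0.243 and 1.82 ± 0.912 CPM for CYP4F2 (SD, n = 3 each). Without mCherry-targeting replicate 1 the log2 fold changes were 2.36 for CYP4F3 and 1.65 for CYP4F2. The reductase gene DHRS2 was 4.77 ± 0.318 and 2.03 ± 0.345 CPM (SD, n = 3 each; log2 fold change -1.23 ± 0.19), and the axonemal dynein gene DNAH17 had a log2 fold change of -1.03 ± 0.23. The edgeR adjusted p was 0.193 for each of the 4. Lower levels were also measured for GPX3 (-0.62 ± 0.12), an extracellular glutathione peroxidase gene, and PIR (-0.79 ± 0.18), which encodes pirin, each with an edgeR adjusted p of 0.193. CYP4F3 and CYP4F2 are close in sequence, so their counts can share reads.

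Libraries differed in a way that the groups do not follow. Non-targeting replicate 1 and mCherry-targeting replicates 1 and 2, which have the lower 7SK shares, set against the other 3 libraries gave 934 called genes and 52 of at least 2-fold, against 2 and 1 for the real split. That points to a structure of the samples, and the labels name no batch. In all, 2 of the 10 splits gave as many called genes and 2 as many of at least 2-fold, while all 10 gave as many called lists as the real 2, with up to 13 in another split; with GC correction 8 of the 10 gave as many lists as the real 8, with up to 14 in another; 10 splits cannot give a share under 0.05. With a term for the library set and GC correction, 40 genes were called, 29 higher and 11 lower. Not all are separated in CPM, as the groups did not overlap in 26 of them. The set was defined from these data, and non-targeting replicate 1 and mCherry-targeting replicate 3 are each alone of their group in their set. The calls include HMOX1, MAP1A, CYP4F3, CYP4F2, DHRS2 and DNAH17, the enolase gene ENO2 (-0.33 ± 0.07), and NCL (0.38 ± 0.08), which encodes the RNA-binding protein nucleolin. Without the term and the correction NCL was at 0.30 ± 0.11 (edgeR adjusted p = 0.235) and ENO2 at -0.48 ± 0.10 (0.193). Of the 9 arrangements that take as many libraries from each set, 1, the real one, gave as many, and the highest other gave 19; 9 arrangements cannot give a share under 0.05. In this fit the ribosome biogenesis list had a camera adjusted p of 2.44e-05 (adjusted p = 0.939 with an estimated correlation).

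The trend with GC content may come from a GC bias that varies between libraries: the largest difference in slope between 2 libraries of a group was 1.16 times the difference of the group means. That is between non-targeting libraries, and within the mCherry-targeting group the largest was 0.364 times, so this rests on 1 group. The unequal spread of the library sets does not account for the whole trend, since the correlation with GC content was -0.49 with a term for the set, against -0.57 without. A rank correlation does not measure the size of the trend. With that term the median of ZNF genes went from 0.12 to 0.063, and that of glycolysis and hypoxia genes from -0.23 to -0.13. Long non-coding genes followed the trend too, with a slope 0.775 times that of protein-coding genes (95% bootstrap interval 0.682 to 0.863). This speaks against a change limited to translated mRNAs but does not decide it. The interval treats genes as units, which are not independent replicates. The class also includes antisense and sense-overlapping genes, whose counts are uncertain without the strand setting. An effect of the crRNA on GC-rich or GC-poor transcripts in general stays open and was not tested, as the group means of the slope differ at the smallest p that 3 against 3 allows.

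HMOX1 and MAP1A were weighed against GC bias and copy number. After GC correction HMOX1 had a log2 fold change of -1.83 ± 0.16 (edgeR adjusted p = 0.00101) and MAP1A one of -0.84 ± 0.13, against -0.96 ± 0.12 before. MAP1A's smaller fold and larger SE left an adjusted p of 0.267, so that its call ended. With GC and length correction the edgeR adjusted p of MAP1A was 0.0292, and with the library set term and GC correction 1.16e-07. That term was defined from these same libraries after they were seen, so the last value is not independent support. Genes within 1 Mb with a mean CPM of at least 5 had median GC-corrected log2 fold changes of -0.044 ± 0.028 (6 genes near HMOX1) and 0.0033 ± 0.026 (25 genes near MAP1A). The lowest neighbour was at -0.13 near HMOX1 and at -0.22 near MAP1A. This argues against a copy number difference of either region as a whole, but neighbours cannot show a change confined to HMOX1 or MAP1A itself. Whether the NRF2 list as a whole was lower stays open: without HMOX1 its GC-corrected median was -0.079 ± 0.049, with p = 0.0273 by camera at the preset and 0.312 at the estimated correlation, and with the library set term and GC correction the list, HMOX1 included, had a median of -0.0042 (camera adjusted p = 0.297). The ± of the medians over neighbouring genes and over the NRF2 list is not the SE of the fit, and genes are not independent replicates. A lower HMOX1 mRNA may follow the crRNA group, as a hypothesis found and tested on the same data.

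A general loss of cytosolic mRNA that spares mitochondrial transcripts was looked for, since Cas13 effectors bound to a target can cut bystander RNA; whether the target was present is not given in the sources used here. Relative to the median nuclear protein-coding gene, mitochondrial mRNAs differed between the groups by -0.061 ± 0.22 on the log2 scale (exact permutation test, two-sided p = 0.7). The error is too wide to exclude a relative rise of 0.3, and a loss that takes all transcripts alike leaves no trace in counts scaled to the library.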
